A study of Mus musculus with 8 samples.

How the data were processed

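Messenger RNA levels were measured with an Affymetrix whole-transcript array in mouse T helper cells of 2 subsets, Th1 and Th17, from Tet2(f/f) mice (wild-type) and from CD2(Cre)Tet2(f/f) mice (Tet2-deficient). There were 8 arrays in 4 groups, with 2 arrays per group that the sample titles call biological replicates. Per the labels, total RNA was extracted with Trizol and labelled with biotin by a terminal labelling kit.

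The deposited values were log2 probe-set signals. The authors' processing notes name GCOS, RMA and Affymetrix Expression Console, without versions, and state neither the order of the steps nor the background and summarization options. RMA normalizes arrays to one another, so the deposited values were used as they stood, without further scaling. The table held 35556 probe sets on every array, with no duplicated array. Signal values have no counting depth, and the number of arrays limits the precision.

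Probe sets were assigned to genes with the platform annotation of 2016, which names 23410 probe sets, and 21698 of those with a single symbol were matched by gene ID to the reference genes of assembly GRCm38. Of the probe sets, 1621 carried several symbols and 12146 had no symbol given, and both kinds were left out of the gene table. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was kept, which left 19938 genes, and no filter on low signal was applied. No platform symbol differed from the reference symbol of its gene ID. List members absent from the gene table under the listed symbol were looked up under a current symbol where one was given.

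Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit on 4 group means and eBayes with an intensity trend, which left 4 residual degrees of freedom and a prior of 8.32 degrees of freedom. The 6 contrasts were Tet2-deficient against wild-type in Th1 cells, the same in Th17 cells, their mean, their difference (the Th17 effect minus the Th1 effect), and Th17 against Th1 in each genotype. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes of a contrast, and a gene was called at an adjusted p under 0.05. No term for replicate number was used, because neither the titles nor the values pair replicates across groups.

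Before the data were examined, 32 gene lists were fixed, covering T helper programs, cytokines, receptors, signalling, metabolism, stress, cell cycle, DNA methylation and markers of other cell types. Of their 826 listed members, 747 were measured. The 31 lists with at least 5 measured genes were tested with camera (limma) at the preset inter-gene correlation of 0.01, in 1 Benjamini-Hochberg family of 186 tests. Camera asks whether a list moves more than the other genes, and was run again with an estimated correlation. The rotation test fry, which asks whether a list's genes move one way on balance, was run beside it.

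Most genes named in the text were chosen by a rule fixed before the data were examined. It took the 8 called genes with the largest fold in each direction for the comparisons of single groups (5 for the mean, the difference and the Tet2-deficient subset contrast), with no overlap between arrays of the groups compared. Where fewer passed, it took genes with the smallest unadjusted p up to 5 per direction, stated as not passing. It further took up to 4 members with the largest change from each list, and 17 genes fixed by name, 15 of which were measured. Within a contrast, p-values were also adjusted over a list, or over these 15 genes, alone. Such passes were not corrected across lists or contrasts, and were not tested again under the alternatives below. Not every gene the rule allows is named, and predicted genes were not named. Actn1, Car9, Ccr7, Cd200, Hk2, Pdcd1 and, in Tet2-deficient cells, Ccr8, Chac1, Il18r1 and Lss were named after their values were seen. So were Ifi209, Klk1b22, Lce3a and Olfr1471, called when an array was left out, and Akr1c18, Dennd3, Gdpd3, Mid1, Npl, Snord82, Tmem267 and Trim12a, which differed between replicates. Some list members were not analysed here.

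Alternatives that were tried were a block on replicate number, a fit on only the arrays of both groups compared, a filter on genes under the median level, all probe sets, the mean of a gene's probe sets, quantile normalization applied again, centring of each array, eBayes without the trend, robust eBayes, array weights, a fold of at least 1.5 and leaving out each array in turn. A covariate for the share of female RNA, computed from the linear Xist signal, was added after the data were seen. A share on a linear scale need not take up sex differences in log2 signals fully.

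The method was tested on simulated data that gave every gene independent normal noise of its estimated spread, with 200 changed genes in each of 10 runs. In Th1 cells it found 70.7% of genes changed 1.5-fold and 99.9% of genes changed 2-fold, and 7.87% of its calls were false. In the contrast of genotypes in Th17 cells, lists of 25 genes shifted by -0.3 on the log2 scale were scored by an unadjusted p under 0.05. They were found in 10 of 10 runs with the preset and with the estimated correlation, and unshifted lists in 2 and 0 of 10 runs. The simulated genes varied independently, and 200 changed genes ease the adjusted threshold, so these rates may be too high for the deposited data. There, 0 of 186 list tests passed with an estimated correlation. Even the Th1 program between wild-type Th17 and Th1 cells failed it, at a camera adjusted p of 1.8e-18 with the preset. Neither a failure of this test nor a preset call alone settles whether a list shifted.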

Results

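Gene expression was measured on 8 arrays, 2 for each combination of subset (Th1 or Th17) and genotype (wild-type or Tet2-deficient). The series asks how Tet2, an enzyme that oxidizes methylated cytosine in DNA, takes part in T helper subset differentiation. Th1 cells are the subset known for interferon-gamma and Th17 cells the subset known for interleukin-17. The median log2 signal of the 19938 genes lay between 6.53 and 6.61 on every array. Pearson correlations across genes, which are not independent replicates, were 0.990 to 0.994 between the arrays of a group and 0.977 to 0.982 between arrays of different subsets. The first principal component held 60.0% of the variance and separated the subsets, and the second held 10.2%, with wild-type Th1 replicate 2 farthest out. Values after ± are standard errors of a log2 fold change unless SD is written, and all groups have n = 2 arrays.

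Tet2, the targeted gene (gene ID 214133, chromosome 3, 133463677 to 133545136 in assembly GRCm38), was read by a single probe set, 10502284. Its log2 signal was 8.08 ± 0.09 (SD, n = 2) in wild-type and 8.05 ± 0.10 (SD, n = 2) in Tet2-deficient Th1 cells. In Th17 cells it was 8.50 ± 0.02 (SD, n = 2) in wild-type and 8.36 ± 0.04 (SD, n = 2) in Tet2-deficient Th17 cells. By array, the Tet2 signal was 8.14 and 8.02 in wild-type Th1, 8.12 and 7.98 in Tet2-deficient Th1, 8.51 and 8.49 in wild-type Th17, and 8.34 and 8.39 in Tet2-deficient Th17 cells. The log2 fold change of Tet2 was -0.03 ± 0.12 in Th1 cells (adjusted p = 0.982) and -0.14 ± 0.12 in Th17 cells (adjusted p = 0.99996). The labels do not say which exons are flanked by loxP sites, and the probes may lie outside the deleted part, so this signal checks nothing about the deletion. Tet1 (0.19 and -0.05) and Tet3 (0.17 and 0.03), the other enzymes of the family, had log2 fold changes that did not pass in Th1 and Th17 cells.

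**Figure D1:**
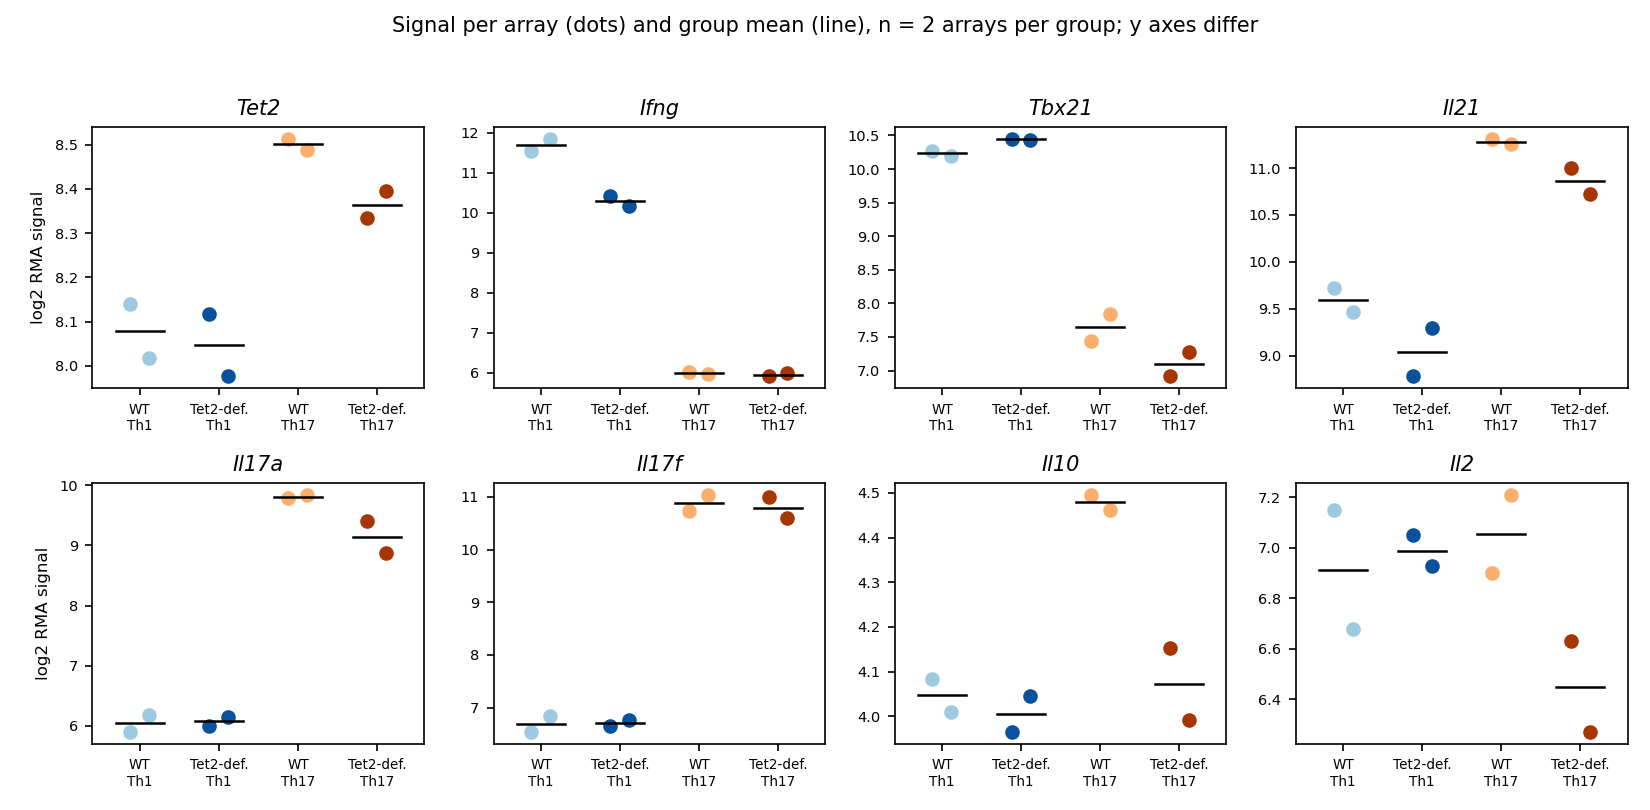
Log2 RMA signal (y axis, a separate scale for each gene) of Tet2, Ifng, Tbx21, Il21, Il17a, Il17f, Il10 and Il2 in the 4 groups (x axis), with a dot for each of the 2 arrays and a line at the group mean. Ifng lies at 11.7 in wild-type and 10.3 in Tet2-deficient Th1 cells and near 6 in both Th17 groups, while Tet2 stays between 7.98 and 8.51 on all arrays.

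In Tet2-deficient Th1 cells, Ifng, which encodes interferon-gamma, fell 2.62-fold against wild-type Th1 cells, with a log2 fold change of -1.39 ± 0.14 (n = 2 and 2, adjusted p = 0.00438, limma). The Ifng signal (gene ID 15978, chromosome 10, probe set 10366586) was 11.5 and 11.8 on the wild-type arrays and 10.4 and 10.2 on the Tet2-deficient arrays. Ifng was the only gene called among the 19938, with 0 genes called higher. An unadjusted p under 0.05 was found for 1206 genes, where chance alone would give 996.9. Of the 15 genes fixed by name, 1 passed adjusted over the list alone, Ifng again (adjusted p = 3.3e-06). Genes with the next smallest p did not pass: Prdm1, which encodes the repressor Blimp-1, had -0.76 ± 0.11 (adjusted p = 0.210) and the cytokine gene Il3 -1.14 ± 0.18 (0.215). Fthl17f had -0.65 ± 0.11 (0.273) and the cytokine gene Il24 -0.83 ± 0.15 (0.379). In the other direction Cypt2 (0.69 ± 0.12), Ripor2 (0.60 ± 0.12), Lce1c (0.69 ± 0.14), Pxdc1 (0.55 ± 0.11) and Wars (0.64 ± 0.14) did not pass, with adjusted p from 0.273 to 0.598. Fthl17f, Cypt2, Lce1c and Pxdc1 lay under the array's median signal on every Th1 array, near background. Tbx21, which encodes the Th1 transcription factor T-bet, had a log2 fold change of 0.21 ± 0.16. Gzmb, which encodes granzyme B, had -0.34 ± 0.20 and Il21 -0.55 ± 0.17, none passing. Il2 (0.08), Il10 (-0.04), Il17a (0.03), Il17f (0.02), Il23r (0.11), Csf2 (-0.29), Il4 (0.07), Gata3 (0.16) and Foxp3 (0.14) did not pass either. The Ifng call ended without wild-type Th1 replicate 2 (-1.24, adjusted p = 0.079) and without Tet2-deficient Th1 replicate 2 (-1.26, adjusted p = 0.141). Without Tet2-deficient Th1 replicate 1 both Ifng and Il3 (-1.43, adjusted p = 0.0369) were called. It also ended in a test of all probe sets (adjusted p = 0.274) and in a fit on the 4 Th1 arrays alone (adjusted p = 0.151).

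Among the gene lists in Th1 cells, camera with the preset correlation called 6 of 31. Of the 6, 0 passed with an estimated correlation, which no list passed in any contrast, and 0 with fry. Cell cycle genes were lower as a set in Tet2-deficient Th1 cells, with 36 of 43 below 0 and a median log2 fold change of -0.24 (adjusted p = 2.1e-09, adjusted p = 0.581 with an estimated correlation). Members named by size, none passing alone, were Bub1 (-0.54) of the spindle checkpoint, the proliferation marker Mki67 (-0.48) and thymidylate synthase Tyms (-0.48). Amino acid stress and ATF4 targets were higher, with 24 of 28 above 0 and a median of 0.19 (adjusted p = 1.4e-05, adjusted p = 0.503 with an estimated correlation), among them Wars (0.64), which passed adjusted over the list alone, and Chac1 (0.53). Immediate early genes, which respond first to stimulation, were higher as a set, with 26 of 29 above 0, none passing, and a median of 0.18 (adjusted p = 3.4e-05, adjusted p = 0.625 with an estimated correlation), as in Maff (0.45) and Fosl1 (0.39). Naive and memory T cell genes had a median of 0.24 with 14 of 20 above 0 (adjusted p = 0.00163, adjusted p = 0.503 with an estimated correlation). Of these, 3 passed adjusted over the list alone, Igfbp4 (0.75) and Bach2 (0.50) higher, and the interleukin-7 receptor gene Il7r (-0.48) against the list's direction. T cell cytokines passed in the downward direction with a mean of -0.12, but the members were split, 18 below and 16 above 0, with a median of -0.02 (adjusted p = 0.0193, adjusted p = 0.610 with an estimated correlation). Ifng, Il3 and Il24 passed adjusted over the list alone, 3 against 1 over all genes. TGF-beta response genes were higher as a set, with 19 of 22 above 0, none passing, and a median of 0.09 (adjusted p = 0.0249, adjusted p = 0.695 with an estimated correlation), as in Smad3 (0.41). The Th1 program itself did not pass (median -0.03, adjusted p = 0.0754). Of its 23 genes, 2 passed adjusted over the list alone in opposite directions, Ifng and the chemokine gene Xcl1 (0.76 ± 0.19). Interferon-stimulated genes did not pass (adjusted p = 0.578), with the interferon-induced protease gene Usp18 at -0.47 and the transcription factor gene Irf1 at 0.58. Without Tet2-deficient Th1 replicate 2 the calls ended for ATF4 targets (adjusted p = 0.0843), naive and memory genes (0.0671) and cytokines (0.133). They ended without wild-type Th1 replicate 1 for cytokines (0.123) and TGF-beta response genes (0.285), and without Tet2-deficient Th1 replicate 1 for the latter (0.594). Without Tet2-deficient Th1 replicate 2 the median was 0.16 for naive and memory genes, 0.22 for TGF-beta response genes and 0.0036 for cytokines. Without Tet2-deficient Th1 replicate 1 it was 0.043 for TGF-beta response genes and -0.042 for cytokines, and without wild-type Th1 replicate 2 -0.0041 for cytokines.

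In Tet2-deficient Th17 cells, no gene passed against wild-type Th17 cells. The closest were Gpr83, a receptor gene known from regulatory T cells, at -0.97 ± 0.13 and Lum, which encodes the matrix protein lumican, at 1.02 ± 0.14 (n = 2 and 2, adjusted p = 0.0582 for both, limma). Il17a, the signature cytokine gene of Th17 cells, had a log2 fold change of -0.67 ± 0.16 (adjusted p = 0.728), with 9.79 and 9.84 on the wild-type arrays and 9.41 and 8.87 on the Tet2-deficient arrays. Il17f had -0.09 ± 0.16 and Il23r, a receptor gene of Th17 cells, -0.22 ± 0.15. Ifng (-0.05), Csf2 (-0.22), Il4 (-0.03) and Gata3 (-0.28) did not pass. Il10, an anti-inflammatory cytokine gene, had -0.41 ± 0.11 (adjusted p = 0.743) and the T cell growth factor gene Il2 -0.60 ± 0.17 (0.789). Tbx21 had -0.55 ± 0.16 (0.789) and Il21 -0.42 ± 0.17 (0.99996). Limma called 0 genes over all genes and 824 had an unadjusted p under 0.05, fewer than the 996.9 that chance would give. Of the 15 genes fixed by name, 4 passed adjusted over the list alone, Il17a, Il10, Il2 and Tbx21, each lower with the same adjusted p of 0.0148. With an array left out, log2 fold changes ranged from -0.94 to -0.41 for Il17a and -0.49 to -0.33 for Il10. They ranged from -0.78 to -0.42 for Il2 and -0.75 to -0.35 for Tbx21. Il10 had a low signal in every group, with means of 4.48 in wild-type and 4.07 in Tet2-deficient Th17 cells, so its difference lies near background. Other genes with small p, none passing, were the chemokine gene Ccl20 (-1.03 ± 0.18), the lymphotoxin gene Lta (-0.96 ± 0.15), Pgf (-0.55 ± 0.11, near background) and Rbl2 (-0.77 ± 0.15). On the other side were Lgr4 (0.77 ± 0.12), the natural killer receptor gene Klrd1 (1.25 ± 0.20), the neutrophil marker Ly6g (0.98 ± 0.17) and Dgat1 (0.75 ± 0.14), with adjusted p from 0.183 to 0.398. Bcl6, which encodes the transcription factor of follicular helper T cells, had 0.75 ± 0.14 (adjusted p = 0.377). Gpr83 and Lum were called with robust eBayes and with array weights, and Gpr83 with a filter on low levels. The array weights were equal for both arrays of a group, 1.27 for Tet2-deficient Th17 and 0.728 for wild-type Th1 cells, so that setting weighted whole groups.

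The Th17 arrays also differed in the sex of the RNA. Xist, the transcript of the inactive X chromosome, had a log2 signal of 5.15 and 10.1 in wild-type and 8.60 and 11.3 in Tet2-deficient Th17 cells. The Y-linked Eif2s3y had 9.65 and 8.46 against 9.36 and 4.33. Setting Xist on Tet2-deficient Th17 replicate 2 to 100%, the female share of the RNA was 0.187% and 42.9% on the wild-type arrays and 14.7% on Tet2-deficient Th17 replicate 1. It lay between -0.130% and 0.105% on the Th1 arrays. Log2 fold changes of Xist (2.32 ± 1.13), Eif2s3y (-2.21 ± 1.05), Uty (-1.65 ± 0.86) and Kdm5d (-0.75 ± 0.54) between genotypes did not pass. These standard errors pool all 4 groups and understate the spread of the Th17 arrays. The SD of Xist was 3.48 in wild-type and 1.89 in Tet2-deficient Th17 cells, against 0.19 and 0.01 in Th1 cells (n = 2 each). Without Tet2-deficient Th17 replicate 1, which leaves the all-female array, 4 genes were called, Eif2s3y, Uty, Klrd1 and Ifi209. Without wild-type Th17 replicate 1, 2 genes were called, Klk1b22 and the olfactory receptor gene Olfr1471. With the female share as a covariate, limma called 0 genes.

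**Figure D2:**
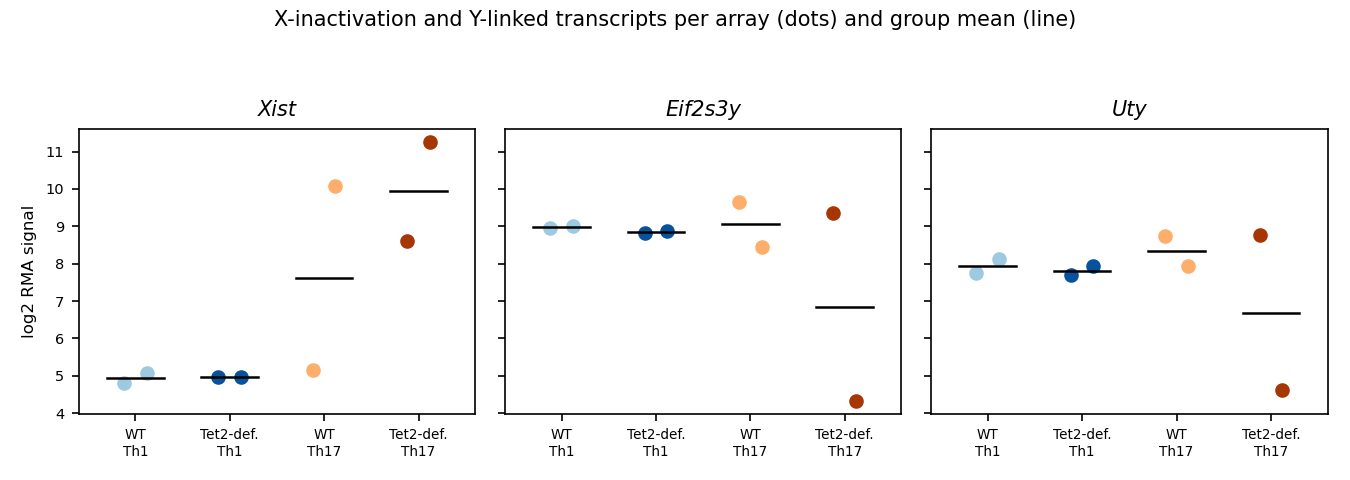
Log2 RMA signal (y axis) of Xist, Eif2s3y and Uty in the 4 groups (x axis), with a dot for each of the 2 arrays and a line at the group mean. Th1 arrays have Xist between 4.80 and 5.07 and Eif2s3y between 8.82 and 9.004, and 1 Tet2-deficient Th17 array has Xist at 11.3 with Eif2s3y at 4.33.

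Camera with the preset correlation called 11 lists in Th17 cells, 5 higher and 6 lower, and 0 of them held with an estimated correlation or with fry. T cell cytokines were lower as a set in Tet2-deficient Th17 cells, with 30 of 34 below 0 and a median of -0.12 (adjusted p = 4.6e-09, adjusted p = 0.503 with an estimated correlation). Il2, Il10, Il17a and Lta passed adjusted over the list alone, 4 against 0 over all genes. The largest others included Tnf (-0.46), which did not pass. Cholesterol and fatty acid synthesis genes were higher as a set, with 27 of 28 above 0, none passing, and a median of 0.20 (adjusted p = 2.0e-08, adjusted p = 0.503 with an estimated correlation). The pathway's genes Hmgcs1 (0.37), Fdps (0.35) and Lss (0.35) did not pass alone. Costimulation and activation genes were lower as a set, with 16 of 22 below 0, none passing, and a median of -0.15 (adjusted p = 1.1e-05, adjusted p = 0.503 with an estimated correlation), as in the receptor gene Tnfrsf9 (-0.60). STAT5 and IL-2 response genes had a median of -0.15 (adjusted p = 0.000106, adjusted p = 0.581 with an estimated correlation). Among them Lta passed adjusted over the list alone, and Socs2, a feedback inhibitor, had -0.55. The Th2 program was lower as a set, with 14 of 16 below 0 and a median of -0.10 (adjusted p = 0.000107, adjusted p = 0.503 with an estimated correlation). The chemokine receptor genes Ccr4 (-0.52) and Ccr8 (-0.42) passed adjusted over the list alone, against 0 over all genes. The Treg program was lower as a set, with 16 of 20 below 0 and a median of -0.09 (adjusted p = 0.000219, adjusted p = 0.503 with an estimated correlation). Gpr83, Tnfrsf9 and Il10 passed adjusted over the list alone, while Foxp3, which encodes the defining transcription factor, had -0.02 ± 0.12. Without wild-type Th17 replicate 2 the calls on the STAT5 (0.616, median -0.014) and Treg lists (0.0661) ended. The median was -0.24 for cytokines, -0.25 for STAT5 genes and -0.15 for the Treg program without wild-type Th17 replicate 1. It was -0.20 for cytokines and 0.095 for cholesterol genes without Tet2-deficient Th17 replicate 1, and without Tet2-deficient Th17 replicate 2 -0.027 for STAT5 genes and -0.053 for the Treg program.

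Of the other 5 lists called in Th17 cells, 4 were higher. Cell cycle genes had a median of 0.09 with 34 of 43 above 0 (adjusted p = 0.00904, adjusted p = 0.722 with an estimated correlation), as in Bub1 (0.44). This direction turned without Tet2-deficient Th17 replicate 2, the all-female array (median -0.10, adjusted p = 0.00946), and the call ended without wild-type Th17 replicate 1 (0.101) and with the female share as a covariate (0.382). The cell cycle median was 0.31 without Tet2-deficient Th17 replicate 1. Natural killer and innate-like cell markers, among the cell types a culture of T cells could hold, had a median of 0.08 with 12 of 16 above 0 (adjusted p = 0.0185, adjusted p = 0.503 with an estimated correlation). Klrd1 and Klrc2 (0.45) passed adjusted over the list alone, and Klrc1 (0.46) did not. Naive and memory T cell genes had a median of 0.09 (adjusted p = 0.0232, adjusted p = 0.581 with an estimated correlation), with Klf3 (0.47) passing adjusted over the list alone and Id3 at 0.55. Interferon-stimulated genes had a median of 0.07 with 22 of 33 above 0 (adjusted p = 0.0263, adjusted p = 0.695 with an estimated correlation), as in Usp18 (0.54), Irf7 (0.42), Oas3 (0.40) and Mx1 (0.37). ATF4 targets were lower, with a median of -0.10 and 21 of 28 below 0 (adjusted p = 0.0225, adjusted p = 0.615 with an estimated correlation). The Th17 program did not pass (median -0.09, adjusted p = 0.0585), with Il17a and Ccl20 lower adjusted over the list alone. Without wild-type Th17 replicate 1 the calls ended for naive and memory genes (adjusted p = 0.760), interferon-stimulated genes (0.766) and ATF4 targets (0.0556), and without wild-type Th17 replicate 2 for natural killer markers (0.134) and ATF4 targets (0.0888). Without Tet2-deficient Th17 replicate 1 they ended for naive and memory (0.518) and interferon-stimulated genes (0.0711), and without Tet2-deficient Th17 replicate 2 for natural killer markers (0.190), ATF4 targets (0.354) and interferon-stimulated genes (0.0587). The naive and memory median was -0.024 and 0.18 without wild-type Th17 replicates 1 and 2 and 0.044 and 0.17 without Tet2-deficient Th17 replicates 1 and 2. The interferon median was 0.025 and 0.16 without wild-type Th17 replicates 1 and 2, the natural killer median 0.13 without wild-type Th17 replicate 1 and the ATF4 median 0.013 without Tet2-deficient Th17 replicate 2.

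**Figure D3:**
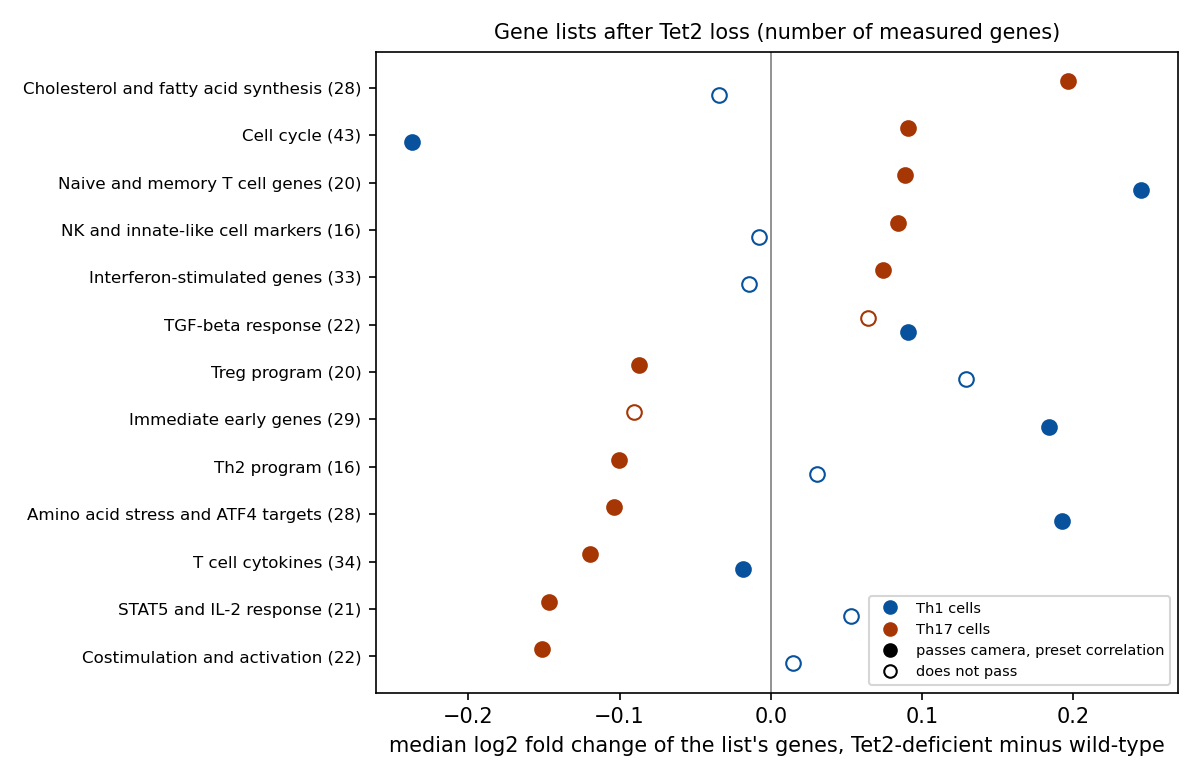
Median log2 fold change of Tet2-deficient minus wild-type cells (x axis) for each gene list that passed camera with the preset correlation in either subset (y axis, number of measured genes in brackets), blue for Th1 and red for Th17 cells, filled where the list passed in that subset. Cell cycle genes lie at -0.24 in Th1 and 0.09 in Th17 cells, and cholesterol and fatty acid synthesis genes at 0.20 in Th17 cells. With an estimated correlation 0 of these calls held, as for every list in every contrast.

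Averaged over both subsets, Tet2-deficient cells had less Ifng (-0.72 ± 0.10) and more Lgr4 (0.59 ± 0.09) than wild-type cells, but neither passed (adjusted p = 0.127 for both, limma, 4 arrays against 4). Gpr83 (-0.60 ± 0.09), Fthl17f (-0.48 ± 0.08, near background) and Ripor2 (0.54 ± 0.08) had an adjusted p of 0.136, and Il24 (-0.63 ± 0.11) and Lta (-0.63 ± 0.11) of 0.209. For Rasa3 (0.55), Tnfrsf14 (0.56) and Lum (0.49) it was 0.275 to 0.461. Limma called 0 genes, and 1093 had an unadjusted p under 0.05. Adjusted over the list alone, 2 of the 15 genes fixed by name passed, Ifng (9.6e-05) and Il21 (-0.49 ± 0.12, 0.0123). T cell cytokines were lower as a set (median -0.10, and -0.065 without wild-type Th17 replicate 2, adjusted p = 1.3e-08, adjusted p = 0.503 with an estimated correlation). Adjusted over the list alone 8 of 34 passed, all lower, against 0 over all genes. Lower sets were also the Th2 program (adjusted p = 0.000285), costimulation genes (0.000478), cell cycle genes (0.0136), STAT5 response genes (0.0232) and the Th1 program (0.0233). Higher sets were the naive and memory genes (0.000119) and cholesterol genes (0.0197). With an estimated correlation, their adjusted p was 0.503 for the Th2 program, costimulation and naive genes, 0.722 for cell cycle, 0.716 for STAT5, 0.545 for the Th1 program and 0.695 for cholesterol genes. The cell cycle call ended without wild-type Th17 replicate 2 (0.0933), wild-type Th1 replicate 2 (0.261), Tet2-deficient Th1 replicate 1 (0.188) and Tet2-deficient Th17 replicate 1 (0.329, with the direction turned). The cholesterol call ended without replicate 1 of wild-type Th17 (0.0583), Tet2-deficient Th17 (0.472), wild-type Th1 (0.0619) or Tet2-deficient Th1 cells (0.178). The STAT5 call ended without wild-type Th17 replicate 2 (0.821), Tet2-deficient Th17 replicate 2 (0.221), wild-type Th1 replicate 1 (0.165) and Tet2-deficient Th1 replicate 2 (0.0599). The Th1 program call ended without wild-type Th17 replicate 2 (0.204), Tet2-deficient Th17 replicate 1 (0.180) and wild-type Th1 replicate 2 (0.168). Without Tet2-deficient Th17 replicate 1, 5 genes were called, Eif2s3y, Uty, Klrd1, Il24 and Lce3a.

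Across the 19938 genes, which are not independent replicates, the correlation of the Tet2 effect in Th1 and Th17 cells was 0.0562 (Pearson) and 0.0510 (Spearman). Without 1 Th17 array, the correlation of the Tet2 effect in Th1 and Th17 cells was -0.040 and 0.123 (wild-type replicates 1 and 2 left out) and -0.0071 and 0.106 (Tet2-deficient replicates 1 and 2 left out). It was 0.0124 without wild-type Th1 replicate 2 and 0.0293 without Tet2-deficient Th1 replicate 2.

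The difference between the subsets in their response to Tet2 loss was tested for every gene. Ifng had the smallest p, with a Th17 effect above the Th1 effect by 1.34 ± 0.19 on the log2 scale (adjusted p = 0.152, limma, n = 2 per group). In Th17 cells the Ifng signal was low in both genotypes (means of 5.999 and 5.95), with a log2 fold change of -0.05 ± 0.14. Limma called 0 genes, with 894 at an unadjusted p under 0.05. Other positive differences that did not pass were Usp18 (1.02 ± 0.16), Prdm1 (0.96 ± 0.16), Lum (1.07 ± 0.19) and Hgsnat (0.90 ± 0.18). Negative differences were those of Ccl20 (-1.26 ± 0.25), the kinase gene Mapkapk3 (-1.14 ± 0.25), Pgf (-0.80 ± 0.15), Ncs1 (-0.79 ± 0.17) and Gucy1b1 (-0.78 ± 0.15), with adjusted p from 0.202 to 0.812. Prdm1 in Th17 cells (means of 5.85 and 6.05) and Lum in Th1 cells (5.22 and 5.17) lay under the array median, near background, where changes shrink. Pgf and Gucy1b1 lay under it in every group. Adjusted over the list alone, 2 of the 15 genes fixed by name passed, Ifng (0.000185) and Tbx21 (-0.76 ± 0.22, 0.0340). The differences of Il17a (-0.71 ± 0.23) and Il2 (-0.68 ± 0.24) did not pass over all genes. Without Tet2-deficient Th17 replicate 1, 4 genes were called, Eif2s3y, Uty, Klrd1 and Alpk2. Camera called 7 lists, and 0 of them with an estimated correlation or fry. The Tet2 effect was higher in Th17 than in Th1 cells for cell cycle genes (median difference 0.35, adjusted p = 2.1e-10, adjusted p = 0.561 with an estimated correlation) and cholesterol synthesis genes (0.28, 8.5e-07, adjusted p = 0.503 with an estimated correlation). It was lower for ATF4 targets (-0.29, 7.7e-07), immediate early genes (-0.24, 1.1e-05), the Treg program (-0.20, 3.7e-05), STAT5 response genes (-0.26, 0.00217) and costimulation genes (-0.16, 0.0263). With an estimated correlation, the adjusted p of these 5 was 0.503, 0.610, 0.503, 0.667 and 0.561. Leaving out an array moved the median to 0.16 for cell cycle genes (Tet2-deficient Th17 replicate 2), to 0.16 or 0.17 for cholesterol genes (Tet2-deficient Th17 replicate 1, Tet2-deficient Th1 replicate 2), to -0.31 for the Treg program (Tet2-deficient Th1 replicate 2) and to -0.17 for STAT5 genes (Tet2-deficient Th1 replicate 1). For immediate early genes it was -0.36 and -0.13 without Tet2-deficient Th17 replicates 1 and 2. The STAT5 call ended, at a median of -0.14, without wild-type (0.458) and Tet2-deficient Th17 replicate 2 (0.0905). The costimulation call ended without the same arrays (0.3001 and 0.177), wild-type Th1 replicate 1 (0.114) and Tet2-deficient Th1 replicate 2 (0.192).

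Wild-type Th17 cells differed from wild-type Th1 cells in the signature genes of both subsets. Ifng was at least 51.7-fold lower in Th17 cells (-5.69 ± 0.14, n = 2 and 2, adjusted p = 2.2e-10, limma), Gzmb 28.8-fold lower (-4.85 ± 0.20) and Tbx21 5.997-fold lower (-2.58 ± 0.16). Il23r was at least 23.1-fold higher (4.53 ± 0.15), Il17f 18.4-fold higher and Il17a at least 13.7-fold higher (3.78 ± 0.16, adjusted p = 4.5e-08). Folds are given as lower bounds where the lower group lay under the array's median signal, near background, which shrinks folds and log2 differences alike. The log2 differences of Iigp1, Serpinb9, Serpinb6b, Il3, Plxnc1 and any other such gene are lower bounds in size for the same reason. Limma called 1675 genes, 990 higher and 685 lower in Th17 cells, and 911 of them had a fold of at least 1.5. That balance was 1223 to 567 with each array centred on its median, 1149 to 420 for genes above the median level and 749 to 626 with quantile normalization again. Other genes lower in Th17 cells were the cytotoxic granule gene Nkg7 (-4.54), the interferon-inducible GTPase gene Iigp1 (-3.52), the protease inhibitor genes Serpinb9 (-3.41) and Serpinb6b (-2.89), Il3 (-3.40) and the semaphorin receptor gene Plxnc1 (-2.92). Other genes higher in Th17 cells were the transcription factor gene Maf (3.67), the proton pump subunit gene Atp6v0d2 (3.14), the leukotriene receptor gene Cysltr1 (3.07), the protease gene Adam19 (2.56) and the kinase gene Alpk2 (2.51). Of the 15 genes fixed by name, 9 passed over all genes and 9 adjusted over the list alone. They included Il21 (1.69 ± 0.17), Il10 (0.43 ± 0.11, adjusted p = 0.0275), Tet1 (0.50 ± 0.11, 0.0169) and Tet2 (0.42 ± 0.12, 0.0429), all higher in Th17 cells, Il10 near background in both, while Il2 (0.14), Csf2 (-0.18), Il4 (-0.17), Gata3 (-0.18), Foxp3 (0.04) and Tet3 (-0.09) did not pass. The Tet2 call ended with each of the 8 arrays left out in turn, at an adjusted p of up to 0.162 without wild-type Th17 replicate 2. With all arrays kept, it also ended with array weights (0.0665), the replicate block (0.0699), the female share as a covariate (0.101), all probe sets (0.107) and quantile normalization again (0.119). A fit on only the wild-type arrays ended it too (0.0945). The Il10 call ended without each wild-type array (up to 0.111) and the Tet1 call without 3 of them (up to 0.0933). Without wild-type Th17 replicate 2, 663 genes were called, and without wild-type Th1 replicate 1, 1029 (529 higher and 500 lower). Xist was 2.68 ± 1.13 in this contrast and did not pass, except without wild-type Th17 replicate 1 (5.14, adjusted p = 0.00172).

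The Th1 program fell as a set in wild-type Th17 cells, with 13 of 23 genes passing, all lower, and a median of -0.88 (adjusted p = 1.8e-18, adjusted p = 0.285 with an estimated correlation). Adjusted over the list alone, 17 of the 23 passed, among them the chemokine genes Ccl3 (-2.48), Ccl4 (-2.19) and Ccl5 (-1.96). With fry the adjusted p was 0.00195. The test with an estimated correlation thus missed a list in which 13 of 23 genes were called. Interferon-stimulated genes were lower, 15 of 33 passing over all genes and 18 lower and 1 higher adjusted over the list alone, with a median of -0.41 (adjusted p = 1.8e-11, adjusted p = 0.503 with an estimated correlation). Usp18 (-2.20), Gbp4 (-2.18) and Irf8 (-2.00) were among them. Cytotoxic effectors were lower as a set, with 7 of 19 genes passing, all lower, and 9 lower and 1 higher adjusted over the list alone (median -0.30, adjusted p = 2.1e-07, adjusted p = 0.503 with an estimated correlation), including the death ligand gene Fasl (-1.73). The Th17 program rose, with 12 of 27 genes higher, including Rora (2.13) and Ccl20 (2.18), and 1 lower (median 0.53, adjusted p = 6.5e-10, adjusted p = 0.503 with an estimated correlation). That gene was Il24 (-2.74 ± 0.15), a cytokine of the interleukin-10 family, and adjusted over the list alone 15 were higher and 1 lower. T cell receptor signalling genes were higher as a set, with 6 of 25 passing, among them the adaptor genes Skap1 (1.39) and Themis (0.99) (median 0.22, adjusted p = 3.4e-05, adjusted p = 0.581 with an estimated correlation). Naive and memory genes had 10 higher, including Igfbp4 (1.66), Lef1 (1.08) and Bach2 (0.89), and 3 lower, Dapl1 (-2.28), Actn1 (-0.68) and the lymph node homing receptor gene Ccr7 (-0.50). Their median was 0.47 (adjusted p = 0.000465, adjusted p = 0.503 with an estimated correlation). With all arrays kept, the Ccr7 call ended with array weights (0.0537), the replicate block (0.0710), the female share as a covariate (0.0865) and all probe sets (0.0942). A fit on only the wild-type arrays ended it too (0.101). The Ccr7 call ended without each Th17 array and without wild-type Th1 replicate 1, at up to 0.210 without wild-type Th17 replicate 1. Without wild-type Th17 replicate 2 the median was 0.22 for the Th17 program and 0.29 for naive and memory genes, and without wild-type Th1 replicate 1 it was 0.14 for T cell receptor genes.

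Further sets passed in this comparison of wild-type cells. Cell cycle genes were lower as a set, with 37 of 43 below 0 and the cyclin genes Ccne1 (-0.69) and Ccne2 (-0.82) passing (median -0.22, adjusted p = 0.000561, adjusted p = 0.717 with an estimated correlation). Glycolysis and hypoxia genes had 7 higher, including Pfkl (0.96), P4ha1 (0.83) and Pdk1 (0.75), and 2 lower, the hexokinase gene Hk2 (-0.47) and the carbonic anhydrase gene Car9 (-0.36). Their median was 0.16 (adjusted p = 0.00476, adjusted p = 0.503 with an estimated correlation). With all arrays kept, the Hk2 and Car9 calls ended with array weights (0.0563 and 0.0781), the replicate block (0.0623 and 0.0675) and the female share as a covariate (0.0785 and 0.0893). They also ended with only the wild-type arrays (0.101 and 0.108). TGF-beta response genes were higher as a set, with 6 of 22 passing, including Smad3 (1.73) and the receptor gene Tgfbr1 (1.15), with a median of 0.13 (adjusted p = 0.0148, adjusted p = 0.680 with an estimated correlation). The Tfh program had 6 higher, including Bcl6 (1.18) and Pou2af1 (1.47), and 2 lower, Pdcd1 (-0.67) and Cd200 (-0.76), which encode inhibitory and regulatory surface proteins. Its median was 0.18 (adjusted p = 0.0263, adjusted p = 0.503 with an estimated correlation). Markers of other cells were lower as sets: myeloid and dendritic cell markers (median -0.16, adjusted p = 0.0119), natural killer markers (-0.16, 0.0263) and B cell markers (-0.13, 0.0284), each with adjusted p = 0.503 with an estimated correlation. In the myeloid list, the macrophage gene Mpeg1 (-0.72) and the dendritic cell factor gene Batf3 (-0.78) passed as lower and Ly6g (0.81) as higher. In the natural killer list Nkg7 passed alone, a gene also in the Th1 program and cytotoxic lists. Of B cell markers 0 passed, with the class II gene H2-Ab1 at -0.84 (adjusted p = 0.0538) and Cd79a, near background, at -0.33. List means lay under the mean of all genes on every array, by log2 values of -1.60 to -1.19 (natural killer), -0.93 to -0.73 (B cell) and -0.83 to -0.64 (myeloid). Many members may thus lie near background, and a share of other cells was not tested.

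Among lists that did not pass between the wild-type subsets, T helper transcription factors had 10 higher and 7 lower, with Prdm1 (-1.63) among the lower (adjusted p = 0.0954). Inhibitory receptors had 5 higher, including the ectoenzyme gene Nt5e (2.36), Cd101 (1.78) and Ctla4 (1.27), and 7 lower (adjusted p = 0.184). Chemokines and their receptors had 4 higher and 6 lower (adjusted p = 0.1496). Fry called 8 lists in this contrast. List calls ended for B cell and TGF-beta genes without wild-type Th17 replicate 2 (both 0.0861) and for B cell (0.0653), natural killer (0.0598) and Tfh genes (0.0550) without wild-type Th1 replicate 2. Without wild-type Th1 replicate 1 they ended for myeloid (0.0745) and B cell markers (0.0503). The median was 0.050 for TGF-beta genes, 0.11 for Tfh genes and -0.10 for myeloid markers without wild-type Th17 replicate 2, and 0.10 for Tfh genes without wild-type Th17 replicate 1. Of single genes, the Car9 call ended with every array left out in turn (up to 0.190) and the Hk2 call with every array but wild-type Th1 replicate 1 (up to 0.164). Without wild-type Th17 replicate 2, calls ended for Ccne1 (0.0672), Ccne2 (0.0633), Cd200 (0.0658), Ly6g (0.1204) and Mpeg1 (0.140), and without wild-type Th17 replicate 1 for Pdk1 (0.0822) and Pdcd1 (0.114). Without wild-type Th1 replicate 1 they ended for Pdk1 (0.0717), Pdcd1 (0.0784), Ly6g (0.0755) and Mpeg1 (0.122), and without wild-type Th1 replicate 2 for Ccne1 (0.0512). H2-Ab1 passed without Tet2-deficient Th1 replicate 1 (0.0136) or 2 (0.0137).

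In Tet2-deficient cells, the same comparison of Th17 with Th1 cells gave lower Ifng (-4.35 ± 0.14, at least 20.4-fold, adjusted p = 3.0e-09, limma, n = 2 and 2), Nkg7 (-4.95 ± 0.19), Gzmb (-4.72 ± 0.20), Iigp1 (-4.00 ± 0.20) and Tbx21 (-3.34 ± 0.16, 10.2-fold), where the values of Ifng, Nkg7 and Iigp1 are lower bounds in size. Higher in Tet2-deficient Th17 cells were Il23r (at least 18.3-fold), Il17f (4.10 ± 0.16), Atp6v0d2 (4.02 ± 0.12, a lower bound), Maf (3.52 ± 0.24) and Il17a (3.07 ± 0.16, at least 8.38-fold). Limma called 2015 genes, 1260 higher and 755 lower in Th17 cells, and 1133 of them had a fold of at least 1.5. That balance was 1660 to 596 with each array centred on its median, 1374 to 531 for genes above the median level and 1104 to 655 with quantile normalization again. Of the 15 genes fixed by name, 7 passed over all genes and 9 adjusted over the list alone. The Th2 transcription factor gene Gata3 was lower in Th17 cells (-0.63 ± 0.16, adjusted p = 0.0239), while Il10 (0.07), Tet1 (0.27) and Tet2 (0.32 ± 0.12, adjusted p = 0.108) did not pass over all genes. Of the genes higher in Th17 cells, 666 were called in both genotypes, where independent calls would share 62.6. Of those higher in Th1 cells, 355 were shared, where independent calls would share 25.9. No gene was called in opposite directions, and across the 19938 genes the log2 fold changes of both genotypes had a Pearson correlation of 0.807 and a Spearman correlation of 0.671. Xist was higher in Tet2-deficient Th17 cells (4.97 ± 1.13, adjusted p = 0.0155), where replicate 2 was all female. That call also ended with robust eBayes (adjusted p = 0.223) and with all probe sets (0.140), and its ± pools groups of unlike spread. With the female share as a covariate 726 genes were called. The count was 801 without Tet2-deficient Th17 replicate 1, 1103 without Tet2-deficient Th17 replicate 2, 933 without Tet2-deficient Th1 replicate 1 and 1204 without Tet2-deficient Th1 replicate 2. The Gata3 call ended without each of these arrays, with an adjusted p of up to 0.190, and the Xist call without the latter 3, up to 0.134, and with the female share as a covariate (2.21, adjusted p = 0.219).

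Camera called 14 lists between the Tet2-deficient subsets, and fry 5. The Th1 program was lower with 17 genes and higher with 1, the receptor gene Il18r1 (0.87), of 23 (median -1.06, adjusted p = 1.6e-16, adjusted p = 0.285 with an estimated correlation). Adjusted over the list alone these were 18 and 2. The Th17 program was higher with 11 genes, including Rora (2.41) and Il21 (1.82), and lower with 2, including Il24 (-2.35) (median 0.30, adjusted p = 1.8e-07, adjusted p = 0.503 with an estimated correlation). Lower sets with an adjusted p of 0.503 under an estimated correlation were interferon-stimulated genes (median -0.31, 1.8e-07), cytotoxic effectors (-0.16, 1.5e-05), ATF4 targets (-0.29, 0.000465) and myeloid markers (-0.14, 0.0299). Serpinb9 was at -2.92, Atf3 at -2.19, Wars at -0.72 and Chac1 at -0.63, and against the direction of its list Ly6g at 1.63. Higher sets with that same value were naive and memory genes (0.46, 0.00163, with Dapl1 at -2.98 against the direction) and glycolysis genes (0.09, 0.00904). Cholesterol synthesis genes were higher (0.19, 0.000104, adjusted p = 0.561 with an estimated correlation), with Dhcr7 (0.89), Elovl6 (0.75) and Lss (0.59) among the 6 of 28 passing. Immediate early genes were lower (-0.37, 0.00127, adjusted p = 0.695 with an estimated correlation), with Nr4a3 at -1.34, and T cell receptor genes higher (0.14, 0.00201, adjusted p = 0.667 with an estimated correlation). The Th2 program was lower (-0.17, 0.00722, adjusted p = 0.561 with an estimated correlation), with Il3 (-2.36) and Ccr8 (-0.68) lower and Ccr4 (1.16) higher. Cytokines (-0.20, 0.0263, adjusted p = 0.625 with an estimated correlation) and STAT5 response genes (-0.29, 0.0263, adjusted p = 0.717 with an estimated correlation) were lower too. Natural killer markers did not pass (0.559), with Klrd1 higher (1.73 ± 0.20, adjusted p = 0.000207), nor did B cell markers (0.119), with H2-Ab1 lower (-1.22, adjusted p = 0.00764). Without Tet2-deficient Th17 replicate 2 the calls ended on STAT5 genes (0.192), cytokines (0.0970) and myeloid markers (0.0756), and the last of these also without Tet2-deficient Th1 replicate 2 (0.0988). Calls on Il18r1, Lss, H2-Ab1, Wars and Chac1 ended too. Il18r1 and H2-Ab1 did not pass without replicate 1 of Tet2-deficient Th17 (0.0907 and 0.0543) or Th1 cells (0.0872 and 0.0672), nor Wars without Tet2-deficient Th17 replicate 2 (0.0659). Lss and Chac1 did not pass without replicate 1 (0.184 and 0.0943) or replicate 2 of Tet2-deficient Th17 cells (0.0622 and 0.180) or without Tet2-deficient Th1 replicate 2 (0.184 and 0.230). With the female share as a covariate, Lss (0.133), Wars (0.0923) and Chac1 (0.264) did not pass. The Th17 program median was 0.17 and 0.49 without Tet2-deficient Th17 replicates 1 and 2, that of T cell receptor genes 0.057 and 0.25, and that of myeloid markers -0.21 without the first. Without Tet2-deficient Th17 replicate 2 the median was -0.13 for STAT5 genes and -0.27 for the Th2 program, and without Tet2-deficient Th1 replicate 1 it was -0.18, -0.089 and, for glycolysis genes, 0.19.

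Lists that bear on DNA methylation did not pass in any of the 6 contrasts. The DNA methylation and demethylation machinery had a median of -0.03 after Tet2 loss in Th1 cells (adjusted p = 0.396) and -0.04 in Th17 cells (0.195). In wild-type Th17 against Th1 cells Tet1, Tet2 and the glycosyltransferase gene Ogt (0.62) were higher and the stress-response genes Gadd45g (-1.08) and Gadd45b (-0.69) lower (list adjusted p = 0.586). The Ogt call ended without wild-type Th17 replicate 1 (0.0778) or wild-type Th1 replicate 1 (0.0508), and the Gadd45b call without wild-type Th17 replicate 2 (0.0521). Germline genes that promoter methylation silences had a median of -0.01 in Th1 cells (adjusted p = 0.927, with a mean of 0.00193 on the other side of 0) and 0.04 in Th17 cells (0.289). Between the Tet2-deficient subsets 1 of 27 passed, Tdrkh (0.96, list adjusted p = 0.464), though not without Tet2-deficient Th1 replicate 1 (0.0554) or with the female share as a covariate (0.0567). Imprinted genes had a median of 0.01 (0.903) and -0.02 (0.542). Of markers for other cells, those of CD8 and gamma-delta T cells (0.313 in Th1, 0.490 in Th17 cells after Tet2 loss) and of red blood cells and platelets (0.185 and 0.586) did not pass in any contrast. Those of B cells (0.586 and 0.949) and myeloid cells (0.740 and 0.282) did not pass after Tet2 loss. Cyclin-dependent kinase inhibitors and p53 targets (0.586 and 0.118) and the unfolded protein response (0.365 and 0.185) did not pass in any contrast. The list of Xist and Y-linked genes had fewer than 5 measured members and was not tested as a set.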

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

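Tests fixed before the data were examined compared the Tet2 effect between Th17 and Th1 cells, while the covariate for female RNA and both tests on Ifng were chosen only after the result was seen. As a set, 7 gene lists responded differently to Tet2 loss in the 2 subsets by camera with the preset correlation. With an estimated correlation 0 of the 7 did, in a test that 0 of 186 passed. The median difference, Th17 minus Th1, was 0.35 for cell cycle genes and 0.28 for cholesterol and fatty acid synthesis genes. It was -0.29 for ATF4 targets, -0.26 for STAT5 and IL-2 response genes, -0.24 for immediate early genes, -0.20 for the Treg program and -0.16 for costimulation genes. Leaving out 1 array moved 5 of these medians by over 1.5 times. They became 0.16 for cell cycle genes and -0.13 for immediate early genes without Tet2-deficient Th17 replicate 2, and 0.16 for cholesterol genes and -0.36 for immediate early genes without Tet2-deficient Th17 replicate 1. They became 0.17 for cholesterol genes and -0.31 for the Treg program without Tet2-deficient Th1 replicate 2, and -0.17 and -0.14 for STAT5 genes without Tet2-deficient Th1 replicate 1 and wild-type Th17 replicate 2. Limma called 0 single genes for this difference over all genes, with 894 at an unadjusted p under 0.05. No cause of the list differences was tested. Adjusted over the genes fixed by name alone, 2 single genes also differed, Ifng (1.34, adjusted p = 0.000185) and Tbx21 (-0.76, adjusted p = 0.0340), and neither passed over all genes.

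The Ifng difference came from a fall of Ifng in Tet2-deficient Th1 cells (-1.39), while Ifng was low in both Th17 groups, where little room was left for a fall. Fewer cells with a Th1 program would have lowered other Th1 genes too, but 10 other Th1 program genes at least 2-fold higher in wild-type Th1 than in Th17 cells had a median of -0.022 (quartiles -0.22 to 0.03), above the bound of -0.69, with Gzmb lowest at -0.34. After quantile normalization was applied again, Ifng stayed at -1.44 ± 0.13. The deposited values were already normalized across arrays, so this test could hardly have moved Ifng and does not decide about array scaling. Outside the Th1 program list, some genes higher in wild-type Th1 than in Th17 cells were also lower in Tet2-deficient Th1 cells, none passing. Their mean signals in wild-type and Tet2-deficient Th1 cells were 8.20 and 7.07 for Il3, 9.59 and 8.76 for Il24 and 7.48 and 6.73 for Prdm1. Of 92 genes that mark Th1 cells over both genotypes, 39 were lower, with a median log2 fold change of 0.026. A lower Ifng transcript level without Tet2, apart from most of the Th1 program, may account for the pattern, as may culture or stimulation that differed between genotypes, which was not tested. The call rests on 2 arrays per group and ended without wild-type Th1 replicate 2 (adjusted p = 0.079) or Tet2-deficient Th1 replicate 2 (0.141).

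Among the Th17 arrays, the share of female RNA differed within both genotypes, as Xist and the Y-linked genes show. If this share were the cause of the Th17 differences between genotypes, a covariate for it would shrink them. It need not remove them, because a share on a linear scale enters a model of log2 signals. For the 27 genes with an unadjusted p under 0.001, Xist and Y-linked genes left out, the median share of the log2 fold change that remained was 0.986 (quartiles 0.941 to 1.03). For 2014 genes called between Tet2-deficient Th17 and Th1 cells, with the same left out, it was 1.02 (0.924 to 1.12). The covariate's slope comes only from differences between replicates of a group, and genes picked by a small p have replicates that agree. Most of the log2 fold change was thus bound to remain, so these shares do not decide the question. Of 2015 calls between Tet2-deficient Th17 and Th1 cells, 696 were among the 726 made with the covariate. The median standard error rose from 0.131 to 0.182, while the median size of the log2 fold change went from 0.616 to 0.640. The covariate also takes up a residual degree of freedom, and what ended the other calls was not tested. Xist, where the explanation holds by construction, went from 4.97 to 2.21. The covariate thus left part of the difference even in the gene it was computed from. The sex of the animals is not a group of this design.

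Probe sets outside the gene table numbered 15618, with several symbols, no symbol or a brighter probe set of the same gene. In a test of all probe sets, 164 of them were called between wild-type Th17 and Th1 cells (30 with several symbols, 23 further probe sets of a gene, 111 with no symbol) and 318 between the Tet2-deficient subsets (60, 43 and 215). Limma called 0 of them in the 4 contrasts of Tet2 loss.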

How the results depend on the processing

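Of the tests in this part, those with a covariate for the share of female RNA were chosen only after the result was seen. Where an array is left out, the lone array of its group is assumed to vary like the other groups. With 2 arrays per group, all tests borrow the spread of other groups and genes. Signal over background limits genes near the floor of the array, where a fall cannot show and folds shrink, as for Ifng in Th17 cells.

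The single Th1 call after Tet2 loss, Ifng, was lost with all probe sets (0 genes) and with only the arrays of both groups (0 genes), at an unchanged fold, and the cause was not tested. Under the other 10 settings, which all keep every array, it was called. In Th17 cells, 1 gene was called with genes above the median level, 2 with robust eBayes and 2 with array weights; the cause was not tested. Leaving out an array gave 0 to 2 genes in Th1 cells, 0 to 4 in Th17 cells, 0 to 5 for the mean of both and 0 to 4 for the difference between them, the last 3 ranges reaching their top without Tet2-deficient Th17 replicate 1.

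Between the wild-type subsets, 1675 genes became 1101 with only both groups' arrays, 1186 with the female share, 1790 with median centring, 1255 with array weights and 911 with a fold of at least 1.5, and 663 to 1551 with an array left out. Between the Tet2-deficient subsets, 2015 became 2346, 726, 2256, 2662 and 1133 under the same settings, and 801 to 2335 with an array left out. With all probe sets tested, 599 and 1001 probe sets were called, of which 435 and 683 were those of genes called above. A replicate block, though the numbers pair nothing, gave 1 gene in Th1 cells, 0 in Th17 cells, 0 for the mean, 0 for the difference, 1398 and 1767. Of 186 list tests, 59 passed with the preset correlation, 0 with an estimated correlation, 13 with fry and 59 with the replicate block. The tests that passed need not be the same under each setting. Without 1 array, the correlation of the Tet2 effect in Th1 and Th17 cells was -0.040 to 0.123.

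Of 95 called results of named genes, 25 lost the call under some setting and 0 reversed. Over all 216 named results, settings other than leaving out an array gave 2309 values, with 2246 unchanged in direction and call, 53 that lost the call, 8 that gained it and 2 that reversed, Il10 in Th1 cells after quantile normalization again (0.0107) and Kdm5d in Th17 cells with the female share (0.23). Leaving out an array gave 1728, with 1622, 71, 8 and 27. None of the genes that reversed had passed, and the cause was not tested. Their ranges after Tet2 loss in Th1 cells were Tet2 -0.10 to 0.040, Il2 -0.16 to 0.31, Il17a -0.11 to 0.18, Il17f -0.13 to 0.16, Il23r -0.062 to 0.29, Csf2 -0.63 to 0.048 and Il4 -0.045 to 0.18. In Th17 cells they were Il17f -0.28 to 0.11, Tet3 -0.025 to 0.091, Il4 -0.097 to 0.045, Foxp3 -0.15 to 0.11, Xist -0.14 to 4.78, Eif2s3y -4.72 to 0.31, Uty -3.73 to 0.42 and Kdm5d -1.96 to 0.47. Between the wild-type subsets they were Gata3 -0.42 to 0.053, Csf2 -0.52 to 0.16, Foxp3 -0.0920 to 0.17 and Il2 -0.093 to 0.38, and between the Tet2-deficient subsets Il10 -0.015 to 0.15.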

Other observations

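Of the tests below, the shuffles of replicate differences were chosen only after the result was seen. A few genes differed by over 2-fold between the replicates of several groups, whatever the genotype. With Xist and the Y-linked genes left out, since the sex of the RNA differed between replicates, 50 genes were over 2-fold apart in any group, and 9 were so in 2 or more groups: Mid1 in 4, Dennd3, Gdpd3 and Trim12a in 3, and Akr1c18, Klk1b22, Npl, Snord82 and Tmem267 in 2. Shuffling the genes among genes of similar level 10000 times gave at most 2, but probe sets that are noisier than others of their level would recur too, so this leaves independent noise of single probe sets open. Donor animals that differ in genetic background may also produce such genes, and neighbouring genes would then differ together. Of these 9 genes, with Xist and the Y-linked genes not counted, 0 pairs lay within 10 genes of each other, with a median of 0 and a highest of 3 in 10000 random draws. The bound set beforehand, no more pairs than the median draw, was wrong for 9 genes, because the median draw has 0 pairs, so background and noise cannot be told apart here.

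A hypothesis that Tet2 loss lowers the genes that mark each subset was also tested, on genes called and at least 2-fold higher in that subset over both genotypes. For 92 genes that mark Th1 cells, the median log2 fold change after Tet2 loss in Th1 cells was 0.026 (quartiles -0.17 to 0.21), with 39 negative (camera p = 0.441 with an estimated correlation, 0.386 with the preset). For 149 genes that mark Th17 cells, it was 0.11 in Th17 cells (quartiles -0.09 to 0.31), with 51 negative and an upward direction (camera p = 0.115 with an estimated correlation, 4.3e-05 with the preset). Most of these 149 genes were thus not lower, but the fixed Th17 program list had a median of -0.09 in the same contrast. The requirement that the lower quartile stay above -0.1 was added after these values were seen. It leaves the Th1 markers undecided, and the Th17 markers meet it so narrowly that no conclusion is drawn for them either.

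Other splits of the 8 arrays into 4 and 4 were counted for the contrasts that compare 4 arrays with 4, except the split along the other factor, which the model also held and which could not be fitted. For genotype averaged over both subsets limma called 0 genes, with 1093 at an unadjusted p under 0.05, and the highest of the other splits gave 1. With 0 real calls all 34 of 34 splits give at least as many by construction, so the count says nothing about chance. For Th17 against Th1 cells averaged over both genotypes it called 4522 genes, a count reached by 1 of 34 splits, the real one, with 1 gene as the highest other. Every other split puts arrays of both subsets on each side, which leaves the subset difference in its residual spread. Low counts there were assured, so the splits do not exclude chance.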
